A study of Rattus norvegicus with 54 samples.

How the data were processed

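The analysis started from the tables deposited with the series: log2 values per gene for the glucose time course (exons and introns), the adenovirus experiment and the knockdowns, and signal values per 500 bp window for ChREBP, MED1 and DNase-seq. Per the submitters' processing notes, the authors aligned reads with STAR to build rn5 (Rnor_5.0), and edgeR and HOMER were named as tools. The versions of these tools were not given in the sources used here, nor were the counting tool, the strand setting and the peak threshold. The deposited gene values are in log2 units: log2 counts per M reads (CPM) as computed by the authors, without division by gene length. Recovering reads from them gave whole numbers for 100% of values within a tolerance of 0.01, and edgeR's TMM-scaled log2 CPM with a prior count of 0.25 came within 0.00138 of the deposited values. The deposited site tables hold signal, which is tags per window multiplied by 1 factor per library. The scaling that the authors used for this signal was not stated, so no library totals are given for sites. Inputs had been counted in the same windows.

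Depth was summed from the recovered reads and covers only reads assigned to genes. It was 8.16 to 15.52 M reads per library for exons of the time course, 3.503 to 6.287 M for introns, 5.328 to 7.009 M for the adenovirus experiment and 4.828 to 7.417 M for the knockdowns. Column headers were paired with samples by time, treatment and letter, except for the knockdowns, whose columns were paired only with a group of siRNA and glucose level. With this, 0 columns stayed without a group. For the knockdowns the letters in the column headers differ from those in the sample titles for several groups, and the header letters are used in all texts. The siCtrl sample at 0 h labelled with removal of ribosomal RNA could therefore not be tied to a column, and no term for it was fitted. A gene was tested when it had at least 1 CPM in 2 libraries of the fit. This left 12724 genes for exons and 13541 for introns of the time course, 12411 for the adenovirus experiment, and 12770 for the knockdowns (12763 in the fit of 12 libraries). The deposited exon values cover 19337 genes and the intron values 16761 genes. Symbols are spelled as in the deposited tables (CCND2 and RORC in capitals). Some genes, such as Ppp1r3c, Tm6sf2, Cttn and Myh9, appear there under 2 spellings, which were kept as 2 genes.

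Genes were tested with limma (3.58.1) on the log2 values, with 1 mean per group and empirical Bayes with trend, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes of a comparison. limma was chosen over a count model because the values are log2 CPM. The threshold was an adjusted p of 0.05. siChREBP and siRORC were compared with siCtrl at each glucose level in a fit of all knockdown groups with replicates, and the interaction is the glucose effect with the siRNA minus that with siCtrl. The siRNAs with 1 library per glucose level were compared with siCtrl in an additive fit of siRNA and glucose level over the 12 libraries whose column letter is A (6 siRNAs at 0 h and 12 h, 1 library each). Their error comes from a model that assumes equal glucose effects for each siRNA. The labels do not say whether replicates are separate cultures, so p-values measure the spread between these samples. Standard errors (SE) are those of limma, and group values are means with standard deviations (SD). Sites were tested with limma on log2 signal with a pseudocount of 1, over all windows of a table. For MED1 limma's prior degrees of freedom were effectively infinite, so that the SEs of the named MED1 sites lie close together (0.44 to 0.45). The p-value of a MED1 site therefore uses a spread taken from all sites and does not measure the spread of its own libraries.

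A gene was named in the texts by rules written before the data were examined: 13 genes always (Mlxipl, Rorc, Mycn, Gata4, Atf4, Bhlhe40, Txnip, Arrdc4, Pklr, Ins1, Ins2, Ccnd2, Mki67), up to 3 members with the largest change from each list with at least 3 members past the threshold, and the 5 largest rises and 5 largest falls with a mean of at least 5 CPM and without overlap between the groups. For sites the 5 with the largest change past the threshold and a mean above the median were named. Where 1 group had no reads, only a lower bound of the fold is given, from 3 reads over the group. Such bounds and the intervals of shares cover counting error only.

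The 20 gene lists were fixed from general knowledge of the genes: ChREBP targets and lipogenesis, glycolysis, pentose phosphate and NADPH, cholesterol synthesis, immediate early genes, DNA replication and G1/S, G2/M and mitosis, ribosome biogenesis and MYC targets, amino acid and ATF4 response, ER chaperones and the XBP1/ATF6 response, beta cell identity and secretion, other islet endocrine cells, circadian clock and ROR family, hypoxia response, p53 and DNA damage, interferon response, oxidative phosphorylation, exocrine pancreas, stroma with endothelium and leukocytes, and RNAs without a poly(A) tail. A list needed 3 measured members. Lists were tested with camera from limma at its preset correlation of 0.01 between genes and again with the correlation estimated from the data, and p-values were adjusted over the lists of a comparison. Of 439 tests 202 passed at the preset value and 14 of these also with the estimated correlation. Where a replicate block was fitted, 165 of 167 calls were kept with it at the preset value. Member counts were also adjusted over the list alone.

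Overlaps between sets of called genes were compared with the product of the shares. Because they share siCtrl libraries, siChREBP with siRORC and the siCtrl glucose effect with siChREBP were also compared with 20 simulations without effects. The single siRNAs share the siCtrl libraries of column letter A, and no simulation was run for them. Site overlap was counted with GenomicRanges (1.54.1) for windows sharing at least 1 base, and again after a shift of 50000 bp. Odds ratios come from Fisher's exact test, once over all sites and once within quintiles of signal. DNase-seq has 1 library per time point and was described without a test, against 10000 random site lists of the same size. Confidence intervals are 95% intervals.

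The methods were first run on simulated tables with known changes, drawn from negative binomial counts with the means, depths and dispersions of the real libraries. Changed genes were taken only from those with a mean of at least 5 CPM, and changed sites from those at or above the median signal. Recovery among weaker genes and sites was not measured. At 12 h in exons, over 12555 genes, 31.34% of changes of 1.5-fold, 74.63% of 2-fold and 100% of 4-fold were found, with 6 false calls among 143. Recovery for the same 3 folds was 32.84%, 89.55% and 98.48% for the adenovirus experiment, 44.78%, 86.57% and 100% for siChREBP at 12 h, 5.97%, 67.16% and 100% for its interaction with glucose, 59.7%, 95.52% and 100% for siATF4, and 19.4%, 67.16% and 95.45% for introns at 12 h. For sites it was low: 0%, 0% and 3.03% for ChREBP at 2 h and 1.493%, 2.985% and 50% for MED1, with 2 false calls among 4 and 2 among 38. Only 66 or 67 genes or sites per fold were changed, among 75430 ChREBP and 52362 MED1 sites. The adjusted threshold is stricter when few sites change, and 14841 ChREBP sites passed at 2 h in the real data. The recovery of sites therefore does not give the power in the real data. When the cholesterol list alone was moved 1.5-fold, that list was called and 0 others were.

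Alternatives were a stricter adjusted p of 0.01, a fold limit of 1.5, no filter on low values, a prior count or pseudocount 10 times as large, a replicate block, TMM scaling over the sites, the 2 compared groups alone, and each library left out in turn. After the data were seen, edgeR (4.0.16) quasi-likelihood and DESeq2 (1.42.0) on recovered reads were added, as were the comparison of sites between 12 h and 2 h, leaving out libraries for the single siRNAs, the fit of all 22 knockdown libraries without a letter term, a crossed pairing for the adenovirus experiment, camera with the replicate block, overlaps of the stronger part of the first table alone and the share of raised MED1 sites at raised ChREBP sites with TMM. The rule for pairing asked for 3 or more pairs in a comparison, each with deviations from the group means that correlate above 0.1. Glucose with siCtrl met it, with 3 pairs of header letters at 0.1462 to 0.2544, and the block gave 4996 genes against 4562. Over the groups in the interaction of siChREBP with glucose most pairs lay above 0.1, but library B of siCtrl at 0 h and of siChREBP at 12 h had 0.04413, and the block gave 540 genes against 309. The interaction of siRORC with glucose had pairs down to -0.07426. Each other comparison of groups with replicates has 2 pairs (0.4829 to 0.6616 for ChREBP sites), and with 2 libraries in both groups each letter gives the same correlation. No sample was left out of the main fits.

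Symbols were matched to the supplied list of rat genes (build GRCr8) only to find small RNA genes inside gene spans. Its Ensembl column is empty, so genes were matched by symbol: 88.42% of the genes raised in introns at 1 h and 93.91% of the tested genes had a match. No rn5 annotation was at hand, so sites are given by position without a gene. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.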

Results

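INS-1E cells, a line of insulin-secreting cells from a rat insulinoma, grown at 11 mM glucose, were kept at 5 mM glucose for 24 h and then given 25 mM glucose for 0, 1, 2, 4 or 12 h. RNA was sequenced after removal of ribosomal RNA, with 2 libraries per time point and separate tables for reads in exons and in introns. ChREBP (gene Mlxipl) is a transcription factor activated by glucose metabolites. A constitutively active form of it (CA-ChREBP) was delivered by adenovirus at 5 mM glucose and compared with green fluorescent protein, 2 libraries each. Small interfering RNAs (siRNAs), which lower the transcript they match, were used against ChREBP and RORC (2 libraries each) and against MYCN, GATA4, ATF4 and BHLHE40 (1 library each), with 3 control libraries (siCtrl), all at 0 h and 12 h of high glucose. The labels give poly(A) selection for the knockdown libraries, except 1 siCtrl sample at 0 h labelled with removal of ribosomal RNA. Binding of ChREBP and of MED1, a subunit of the Mediator complex that links transcription factors to RNA polymerase, was measured by chromatin immunoprecipitation at 0, 2 and 12 h with 2 libraries per time. DNase-seq, which counts cuts by DNase I in open chromatin, had 1 library per time. Depth in genes was 8.16 to 15.52 M reads for exons and 3.503 to 6.287 M for introns of the time course, 5.328 to 7.009 M for the adenovirus experiment and 4.828 to 7.417 M for the knockdowns. Replicates of the exon libraries correlated at 0.9501 to 0.9903, those of ChREBP at 0.5875 (0 h), 0.7745 (2 h) and 0.864 (12 h), and those of MED1 at 0.9169 to 0.9191.

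**Figure D1:**
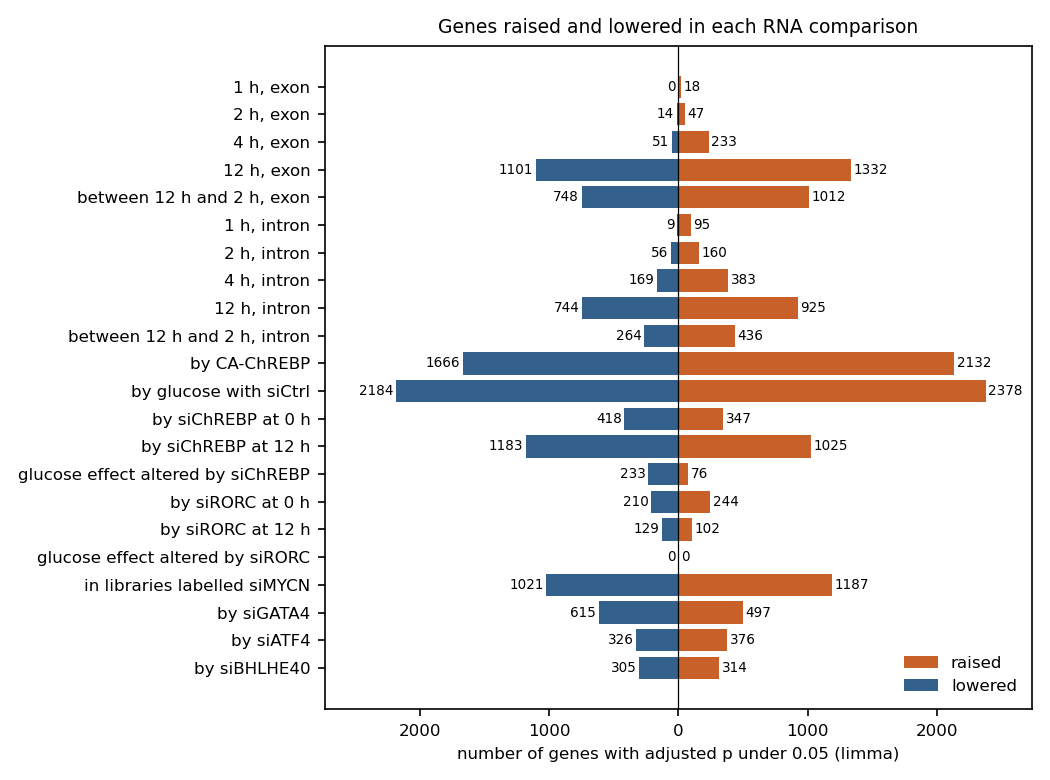
Number of genes raised (right) and lowered (left) with an adjusted p under 0.05 in each RNA comparison, tested with limma; bars are gene counts. High glucose raised 18 genes in exons at 1 h and 1332 at 12 h, and CA-ChREBP raised 2132.

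The first question was which transcripts answered high glucose within 1 h. Txnip, whose protein inhibits thioredoxin and glucose uptake, rose by 6.74±0.13 log2 in exon reads (602.7±24.7 v 5.616±0.5292 CPM, n = 2 v 2, adjusted p = 6.86e-12). Ppp1r3c, which targets a phosphatase to glycogen, rose by 3.90±0.20, Hbegf, a growth factor, by 2.28±0.18, and Bhlhe40, a transcriptional repressor, by 1.81±0.14 (498.4±31.58 v 143.2±27.71 CPM). Mycn had 0.73±0.19 (adjusted p = 0.463), RORC 0.59±0.14 (adjusted p = 0.358), and Ins1 -0.10±0.17 (adjusted p = 1). Among ChREBP targets and lipogenic genes 2 of 23 rose and 0 fell (adjusted p = 6.948e-06 for the list, adjusted p = 0.239 with an estimated correlation). Of 32 immediate early genes 1 passed, while 8 rose and 2 fell when adjusted over the list alone (adjusted p = 5.163e-07 for the list, adjusted p = 0.1252 with an estimated correlation). For cholesterol synthesis 0 of 22 genes passed, although the list was called (adjusted p = 6.654e-06, adjusted p = 0.1252 with an estimated correlation). By limma 18 genes rose and 0 fell, while DESeq2 called 32 raised and 10 lowered genes and limma with a replicate block 33 and 6. Without library A of 0 h 8 genes passed.

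Intron reads of the same hour were tested as well. Txnip rose by 6.88±0.22 (216±29.08 v 1.841±0.7119 CPM, n = 2 v 2, adjusted p = 2.05e-11), Prok2, a secreted peptide, by 4.66±0.23, and Tada3, part of histone acetylation complexes, by 4.38±0.30 (2308±118.6 v 110.9±2.754 CPM). Tada3 and Pfkfb3 have a small RNA gene in their span, and in exons at 12 h Tada3 had -0.15 (adjusted p = 0.526). Intron reads of genes of glucose and sterol metabolism rose: Pfkfb3, which makes an activator of glycolysis, by 2.46±0.19, Eno1, an enolase, by 1.22±0.19, Pklr, the pyruvate kinase of liver and beta cells, by 1.02±0.19, Hmgcs1, an early enzyme of cholesterol synthesis, by 1.03±0.16, and Insig1, a sensor of sterols, by 0.95±0.14. Falls were seen for Lrfn5 (-2.98±0.38), Gfi1b (-2.06±0.33), Fcgr2a (-1.79±0.20), Adcy8 (-1.44±0.30) and Neu3 (-1.44±0.25). Of 25 ChREBP targets 4 rose, 7 when adjusted over the list alone (adjusted p = 1.863e-09, and 0.0313 with an estimated correlation), among them Scd, which desaturates fatty acids, by 0.92±0.14. Of 22 cholesterol genes 4 rose, 13 when adjusted over the list alone (adjusted p = 2.1e-19, and 0.0313 with an estimated correlation), among them Sqle by 0.80±0.16. In glycolysis 5 of 22 rose (adjusted p = 5.655e-11 for the list, adjusted p = 0.09888 with an estimated correlation). limma called 95 raised and 9 lowered genes, and 39 in total passed without library A of 0 h.

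What changed by 2 h in exon reads was asked next. Txnip stood at 660.6±18.25 CPM, a rise of 6.88±0.13 (n = 2 v 2, adjusted p = 5.37e-12), Prok2 rose by 4.13±0.34, Kcnab3, a potassium channel subunit, by 2.78±0.28, and Gata4, a transcription factor of endoderm and heart, by 1.21±0.20 (23.77±0.8192 v 10.23±0.554 CPM). Falls came for Hist2h2ac, a histone gene (-2.18±0.32, 140.7±12.29 v 638.6±21.26 CPM), Scand1 (-1.83±0.23), Bloc1s3 (-1.82±0.29), Tmem238 (-1.66±0.23) and Nrtn (-1.56±0.24). Immediate early genes had 3 of 32 raised and 1 lowered, 10 and 2 when adjusted over the list alone, with Sik1 at 1.87±0.24 and Junb at 1.47±0.25 (adjusted p = 9.431e-07 for the list, adjusted p = 0.1796 with an estimated correlation). ChREBP targets had 3 of 23 raised, 8 when adjusted over the list alone, with Gpd1, which makes the glycerol backbone of lipids, at 1.06±0.15 and Klf10 at 0.78±0.15 (adjusted p = 1.151e-09, adjusted p = 0.1796 with an estimated correlation). Cholesterol synthesis had 1 of 22 raised, 5 when adjusted over the list alone (adjusted p = 4.302e-11, and 0.0418 with an estimated correlation). RNAs without a poly(A) tail had 1 of 34 lowered, 8 when adjusted over the list alone (adjusted p = 9.915e-12, adjusted p = 0.2227 with an estimated correlation). Over all genes limma called 47 raised and 14 lowered, and 17 passed in total without library A of 0 h. In introns 160 rose and 56 fell, among them Mycn with 1.41±0.33 (adjusted p = 0.041) and Ldlr, the receptor for low density lipoprotein, with 0.81±0.13, and 65 passed without library A of 0 h.

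Exon reads at 4 h were used to ask which further genes had moved. Mycn rose by 1.58±0.19 (24.94±0.8177 v 8.324±0.3675 CPM, n = 2 v 2, adjusted p = 0.000397), RORC, a nuclear receptor, by 1.20±0.14, CREM, a factor of the cyclic AMP response, by 1.61±0.23, and CCND2, a cyclin of G1, by 0.97±0.20. Pklr rose by 1.61±0.14, Gpd1 by 2.26±0.15, and Arrdc4, a relative of Txnip, by 0.69±0.12, while Ogt, which attaches N-acetylglucosamine to proteins, fell by 1.44±0.17 (68.73±2.624 v 186.9±20.77 CPM) and Zbtb20 fell by 1.34±0.27. Atf4 had 0.50±0.16 (adjusted p = 0.167). ChREBP targets had 9 of 23 raised (adjusted p = 9.066e-12, adjusted p = 0.1194 with an estimated correlation). Ribosome biogenesis had 4 of 34 raised, with Srm at 0.98±0.21 and Nolc1 at 0.62±0.14 (adjusted p = 8.346e-06, adjusted p = 0.05107 with an estimated correlation). Cholesterol synthesis had 3 of 22 raised, 9 when adjusted over the list alone, with Dhcr7 at 0.64±0.12 and Ldlr at 0.48±0.11 (adjusted p = 3.115e-09, adjusted p = 0.05107 with an estimated correlation). limma called 233 raised and 51 lowered genes, and leaving out 1 library gave 96 (without 0 h A) to 135 (without 0 h B). In introns 383 rose and 169 fell, 188 in total without library A of 0 h, and 10 of 25 ChREBP targets rose, 14 when adjusted over the list alone (adjusted p = 4.513e-11, and 0.03792 with an estimated correlation). E2f1, a driver of S phase, rose by 3.30±0.67 in introns, with a wide spread (9602±10480 v 625±92.2 CPM).

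**Figure D2:**
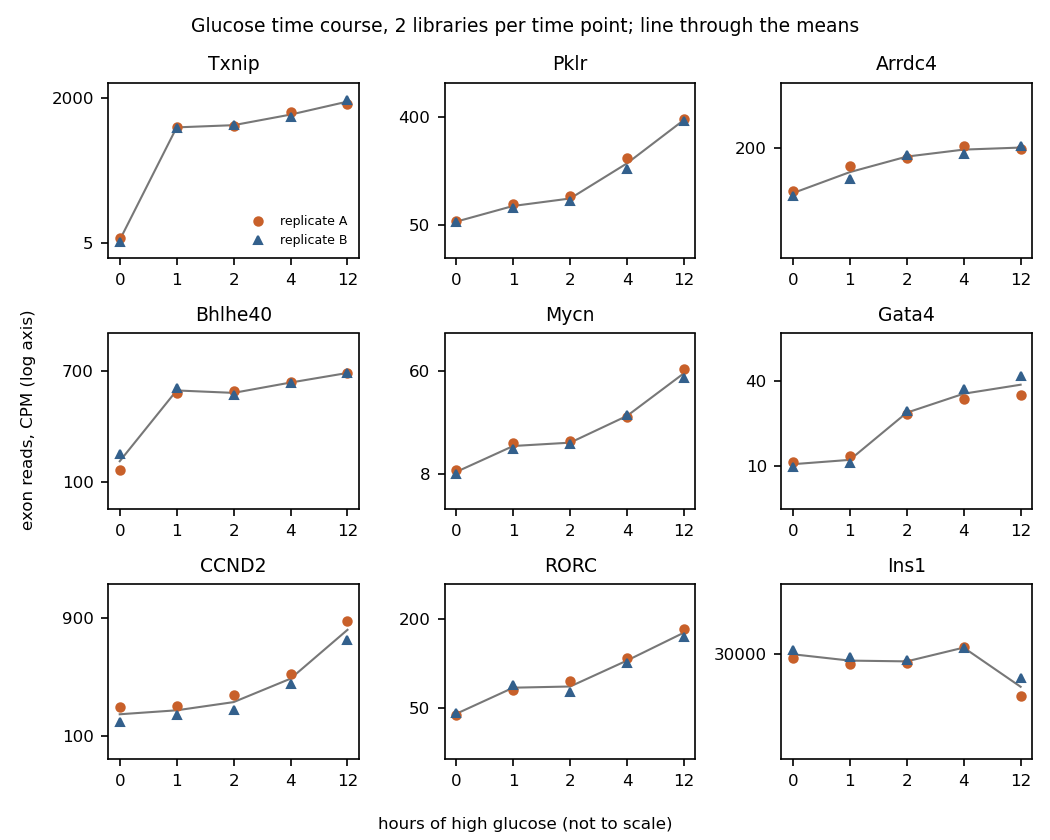
Exon reads in CPM (log axis) against hours of high glucose for 9 genes; points are the 2 libraries per time point and lines join means. Txnip went from 5.616 CPM at 0 h to 602.7 CPM at 1 h and 1759 CPM at 12 h, while Mycn went from 8.324 to 57.52 CPM over the 12 h.

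By 12 h the response in exon reads was broad, and the question was which functions it covered. Txnip reached 1759±201.5 CPM, a rise of 8.28±0.13 (n = 2 v 2, adjusted p = 5.12e-13), Prok2 rose by 6.89±0.34 (153.3±11.85 v 1.36±0.7002 CPM), Kcnab3 by 5.91±0.28, and S100a4, a calcium binding protein, by 6.31±1.00. Mycn rose by 2.78±0.19 (57.52±7.053 v 8.324±0.3675 CPM), CCND2 by 2.27±0.20, Bhlhe40 by 2.26±0.14, Gata4 by 1.86±0.20, RORC by 1.82±0.14 and Atf4, the factor of the amino acid response, by 0.97±0.16. Ins1 and Ins2, the insulin genes of the rat, fell by 0.52±0.17 (21040±2896 v 30030±1800 CPM, adjusted p = 0.0471) and by 0.52±0.15 (adjusted p = 0.0305). F3, tissue factor, fell by 2.56±0.22, Isoc2a fell by 2.58±0.34 and Ttc38 fell by 2.39±0.21. Mlxipl itself had 0.43±0.18 (adjusted p = 0.12) and Mki67, a marker of dividing cells, 0.68±0.34 (adjusted p = 0.183).

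DNA replication and G1/S had the largest share of raised genes at 12 h. Of 37 genes 32 rose and 0 fell, 34 and 1 when adjusted over the list alone, with Cdc6, which loads the replicative helicase, at 1.99±0.25 and Orc1, of the origin complex, at 1.93±0.40 (adjusted p = 4.574e-22, and 0.03157 with an estimated correlation). In cholesterol synthesis 15 of 22 rose, 19 when adjusted over the list alone, with Idi1 at 1.59±0.25 and Pmvk at 1.33±0.16 (adjusted p = 5.041e-11, and 0.0212 with an estimated correlation). In ribosome biogenesis and MYC targets 16 of 34 rose, 18 when adjusted over the list alone, with Odc1, the first enzyme of polyamine synthesis, at 1.80±0.12 and Myc at 1.71±0.45 (adjusted p = 1.135e-08, and 0.0212 with an estimated correlation). Beta cell identity had 2 raised and 14 lowered of 39, 2 and 18 when adjusted over the list alone. Among the lowered were Mnx1 (-1.54±0.15, 29.9±3.713 v 86.74±5.195 CPM) and Nkx2-2 (-1.26±0.13), both factors that keep beta cells, and Ucn3, a peptide of mature beta cells (-2.72±0.69), with an adjusted p = 0.0001926 for the list, and 0.03157 with an estimated correlation.

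Further lists at 12 h were called only with the preset correlation. ChREBP targets had 11 raised and 1 lowered of 23, 12 and 1 when adjusted over the list alone, with Gpd1 at 2.90±0.15 and Pklr at 2.82±0.14 (adjusted p = 3.532e-10, adjusted p = 0.08531 with an estimated correlation). Glycolysis had 8 raised and 1 lowered of 22, with Pfkfb3 at 2.49±0.18 (adjusted p = 0.0005378, adjusted p = 0.3979 with an estimated correlation). The pentose phosphate list had 3 raised and 1 lowered of 10, with Tkt, the transketolase, at 2.02±0.13 and Rpia at 0.95±0.15 (adjusted p = 0.01895, adjusted p = 0.1103 with an estimated correlation). The amino acid and ATF4 response had 13 raised and 2 lowered of 35, with NUPR1 at 2.82±0.21, Psph at 1.80±0.16 and Psat1 at 1.74±0.18, the latter pair being enzymes of serine synthesis (adjusted p = 0.0004563, adjusted p = 0.08932 with an estimated correlation). G2/M and mitosis had 12 of 42 raised, 20 when adjusted over the list alone, with Ttk at 1.39±0.33 and Bub1b at 1.24±0.17 (adjusted p = 2.086e-07, adjusted p = 0.3827 with an estimated correlation). The interferon response had 1 raised and 5 lowered of 18, with Irf9 at -1.10±0.21 and Irf7 at 0.97±0.27 (adjusted p = 0.006088, adjusted p = 0.08531 with an estimated correlation). RNAs without a poly(A) tail had 11 raised and 1 lowered of 34, with Hist1h1a at 1.21±0.19 and Hist2h2ac lowered (226.1±32.22 v 638.6±21.26 CPM), adjusted p = 0.007348 for the list (adjusted p = 0.5443 with an estimated correlation).

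The remaining lists were not called at 12 h. Immediate early genes had 7 raised and 4 lowered of 32 (adjusted p = 0.2698), among them Atf3 at 1.98±0.38. ER chaperones had 1 raised and 5 lowered of 31 (adjusted p = 0.4607), with Sdf2l1 at -1.48±0.17, Ero1lb at -1.02±0.13 and Herpud1 at 0.60±0.16. Circadian genes had 4 raised and 2 lowered of 20 (adjusted p = 0.2904), with Hlf at 1.89±0.35. Hypoxia genes had 4 raised and 1 lowered of 19 (adjusted p = 0.1617), with Adm at 1.80±0.23 and Ddit4 at -1.01±0.29. The p53 list had 4 raised and 2 lowered of 16 (adjusted p = 0.5108), with Gadd45a at 1.80±0.20 and Gdf15 at -3.10±0.73, and its median (-0.05) and mean (0.12) differed in sign. Oxidative phosphorylation had 3 raised and 1 lowered of 34 (adjusted p = 0.1399). Markers of other islet cells (0 of 3, adjusted p = 0.5901), of exocrine pancreas (1 of 4 lowered, adjusted p = 0.1617) and of stroma, endothelium and leukocytes (0 of 3, adjusted p = 0.6774) were not past the threshold. In all, limma called 1332 raised and 1101 lowered genes in exons at 12 h. Leaving out 1 library gave 1021 (without 0 h B) to 2966 (without 12 h B) genes.

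Intron reads at 12 h were tested as well. Txnip rose by 8.46±0.22 (652.6±148.3 v 1.841±0.7119 CPM, n = 2 v 2, adjusted p = 8.37e-13), Prok2 by 7.72±0.23, Rasgrp2, an activator of Rap1, by 5.58±0.25, and Mcm5, part of the replicative helicase, rose from 68.43±2.706 to 255.5±7.238 CPM (adjusted p = 3.32e-07). Ins1 fell by 0.72±0.15 (adjusted p = 0.00503), Ins2 fell by 0.61±0.15, Glis3, a regulator of the insulin genes, fell by 1.21±0.16 and Ttc12 fell by 2.95±0.39. DNA replication had 26 of 38 raised, 34 raised and 2 lowered when adjusted over the list alone (adjusted p = 3.26e-24, and 0.01474 with an estimated correlation), and 11 of 25 ChREBP targets rose (adjusted p = 6.573e-09, and 0.03486 with an estimated correlation). limma called 925 raised and 744 lowered genes, 608 in total without library A of 0 h. Of the genes raised in introns at 12 h and measured in both tables, 646 of 880 were also raised in exons, counted in the same libraries. At 1 h this was 11 of 87, with a median exon change of 0.21 for those genes.

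The comparison of 12 h with 2 h asked which genes moved late. Rasgrp2 rose by 4.44±0.34 (150.1±9.168 v 6.951±1.17 CPM, n = 2 v 2, adjusted p = 8.18e-06), Acaca, which makes malonyl-CoA for fatty acids, by 2.17±0.18, Mycn by 1.96±0.19, Mki67 by 1.52±0.34, Txnip by 1.41±0.13 and RORC by 1.21±0.14. Pdx1, a master factor of beta cells, fell by 0.70±0.15 (281.6±51.96 v 455.1±70.06 CPM), Btg2 fell by 0.92±0.16, Sik1 fell by 0.79±0.24, Per3, of the clock, fell by 1.30±0.34, Vdr fell by 2.22±0.43 and Ttc12 fell by 2.02±0.23. DNA replication had 34 of 37 raised (adjusted p = 1.373e-24, and 0.03342 with an estimated correlation), beta cell identity 1 raised and 9 lowered of 39 (adjusted p = 1.657e-05, and 0.03126 with an estimated correlation), and ribosome biogenesis 16 of 34 raised (adjusted p = 7.914e-08, and 0.03126 with an estimated correlation). RNAs without a poly(A) tail had 20 of 34 raised, mostly histone genes such as Hist1h2ail at 1.31±0.17 (adjusted p = 2.61e-10, adjusted p = 0.2502 with an estimated correlation). limma called 1012 raised and 748 lowered genes. Leaving out 1 library gave 685 (without 2 h B) to 2337 (without 12 h B). In introns 436 rose and 264 fell, with 253 in total without library B of 2 h, and 29 of 38 DNA replication genes rose, E2f2 by 2.02±0.34 (adjusted p = 2.291e-28, and 0.01013 with an estimated correlation).

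Whether active ChREBP alone moved these genes at 5 mM glucose was asked with the adenovirus. Txnip rose by 7.82±0.20 (1904±71.62 v 8.739±3.385 CPM, n = 2 v 2, adjusted p = 2.06e-10), Gpd1 by 4.10±0.13, Mycn by 3.42±0.17 (109.2±8.293 v 10.22±1.249 CPM), Pklr by 3.38±0.12 and CCND2 by 2.23±0.12. Gata4 rose by 2.14±0.18, Bhlhe40 by 1.98±0.11, RORC by 1.70±0.14, Atf4 by 1.27±0.14 and Mki67 by 0.92±0.15, while Arrdc4 had 0.16±0.11 (adjusted p = 0.297). Mlxipl was higher by 1.44±0.14, but the virus carries a form of this gene. Reads of the virus and of the cells' own Mlxipl were not told apart. Prdm8 fell by 3.31±0.39 (1.484±0.4082 v 14.86±0.5728 CPM), Lrrc10b fell by 3.44±0.67, Csf1, a growth factor of macrophages, fell by 2.88±0.45, Ins1 fell by 0.62±0.20 (adjusted p = 0.0294) and Ins2 fell by 0.64±0.19 (adjusted p = 0.0208).

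With CA-ChREBP none of the lists kept its call with an estimated correlation. DNA replication had 34 raised and 1 lowered of 38, 36 and 1 when adjusted over the list alone, with Orc1 at 2.33±0.29 (adjusted p = 1.086e-14, adjusted p = 0.2221 with an estimated correlation). Ribosome biogenesis had 26 raised and 1 lowered of 34, with Odc1 at 2.65±0.11 and Ncl, nucleolin, at 1.64±0.15 (adjusted p = 1.838e-12, adjusted p = 0.2064 with an estimated correlation). Cholesterol synthesis had 17 of 22 raised, with Idi1 at 1.93±0.15 (adjusted p = 8.497e-09, adjusted p = 0.2064 with an estimated correlation). The amino acid response had 20 raised and 1 lowered of 36, with Psph at 3.09±0.12 (adjusted p = 6.617e-07, adjusted p = 0.2683 with an estimated correlation). Beta cell identity had 4 raised and 24 lowered of 39, with Mnx1 at -2.48±0.18 and Nkx6-1 at -1.93±0.23 (adjusted p = 3.492e-08, adjusted p = 0.2221 with an estimated correlation). Called as well were ChREBP targets (11 raised and 2 lowered of 23, adjusted p = 1.372e-05, adjusted p = 0.3007 with an estimated correlation) and G2/M (20 of 42 raised, adjusted p = 0.0001469, adjusted p = 0.4751 with an estimated correlation). So were interferon genes (1 raised and 7 lowered of 19, adjusted p = 0.006772, adjusted p = 0.2683 with an estimated correlation) and oxidative phosphorylation (9 raised and 1 lowered of 34, adjusted p = 0.008143, adjusted p = 0.3947 with an estimated correlation). limma called 2132 raised and 1666 lowered genes, 2330 in total without library B of the control virus.

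In the knockdown experiment the siCtrl libraries gave a further view of glucose at 12 h against 0 h. Txnip rose by 6.13±0.25 (1635±382.1 v 23.64±7.244 CPM, n = 3 v 3, adjusted p = 4.08e-10), Prok2 by 6.40±0.55, Mycn by 2.93±0.21 (46.44±7.303 v 6.22±2.135 CPM), Gpd1 by 2.81±0.19, Pklr by 2.79±0.16 and RORC by 1.66±0.12. Baiap3, which acts in the release of dense core vesicles, fell by 2.38±0.14 (33.83±3.452 v 176.4±12.47 CPM), Dbp, of the clock, fell by 2.09±0.31, Nkx2-2 fell by 1.32±0.10 and Ins2 fell by 0.52±0.16. Ins1 had -0.36±0.18 (adjusted p = 0.123) and Mlxipl 0.08±0.12 (adjusted p = 0.634). DNA replication had 35 of 38 raised (adjusted p = 8.159e-19, adjusted p = 0.1473 with an estimated correlation), cholesterol synthesis 21 of 22 (adjusted p = 1.124e-10, adjusted p = 0.1578 with an estimated correlation) and ribosome biogenesis 20 of 34 (adjusted p = 2.491e-08, adjusted p = 0.1473 with an estimated correlation). Beta cell identity had 3 raised and 20 lowered of 39 (adjusted p = 2.618e-05, adjusted p = 0.1578 with an estimated correlation). limma called 2378 raised and 2184 lowered genes. Across genes the changes correlated with those of the time course at 0.778.

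The transcript aimed at was looked up first for every siRNA. Mlxipl stood at 311±35.2 CPM with siChREBP against 554.8±36.85 with siCtrl at 0 h (56.05%) and at 285.7±13.64 against 585±21.91 at 12 h (48.83%). RORC was at 21.83% of siCtrl at 0 h and 23.49% at 12 h with siRORC. Gata4 was at 48.94% and 54.59% with siGATA4, and Atf4 at 42.45% and 41.08% with siATF4. With siBHLHE40 the Bhlhe40 transcript was at 82.43% (147.2 CPM within the siCtrl range of 79.69 to 229) and 76.95% (556.5 CPM below the siCtrl range of 677 to 763.4), and its fall was not past the threshold (-0.51±0.17, adjusted p = 0.102). In the libraries labelled siMYCN the Mycn transcript at 0 h was 10.21 CPM against 6.22±2.135 with siCtrl, or 164.2%, above every siCtrl library (4.849 to 8.68), which goes against the label. At 12 h it was 20.23 against 46.44±7.303, or 43.56%.

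**Figure D3:**
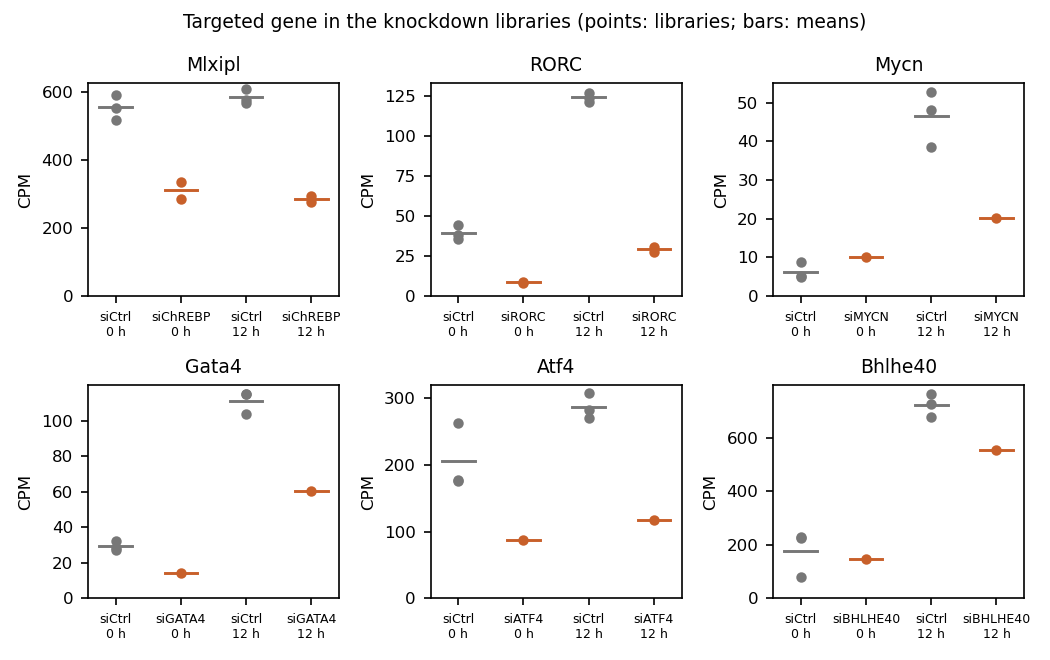
Exon reads in CPM of the targeted gene with siCtrl and with its siRNA at 0 h and 12 h of high glucose; points are libraries (3 siCtrl, 2 or 1 per siRNA) and bars are means. Mlxipl was at 56.05% and 48.83% of siCtrl, while Mycn at 0 h was at 164.2%.

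The effect of siChREBP was first asked at 0 h. Mlxipl fell by 0.84±0.13 (n = 2 v 3, adjusted p = 0.00152), Gpd1 fell from 70.43±1.552 to 29.65±1.557 CPM, Pklr fell by 0.66±0.18, RORC fell by 0.56±0.13 and Id4, an inhibitor of differentiation, fell by 2.36±0.23 (2.296±0.03416 v 12.16±2.75 CPM). Mycn rose by 1.03±0.23 (12.37±1.433 v 6.22±2.135 CPM), Fbln2, of the matrix, by 2.52±0.36 and Ngfr, a neurotrophin receptor, by 2.40±0.40. Txnip had -0.85±0.28 (adjusted p = 0.0895). DNA replication had 13 of 38 raised, 23 when adjusted over the list alone, with Ccne1 at 1.02±0.17 (adjusted p = 6.292e-13, adjusted p = 0.3536 with an estimated correlation). G2/M had 14 of 42 raised, 23 when adjusted over the list alone, with Bub1 at 0.89±0.13 (adjusted p = 4.44e-14, adjusted p = 0.4695 with an estimated correlation). RNAs without a poly(A) tail had 3 of 19 raised, 12 when adjusted over the list alone (adjusted p = 2.998e-07, adjusted p = 0.2206 with an estimated correlation). The labels give poly(A) selection for these libraries, but removal of ribosomal RNA for a siCtrl sample at 0 h. How far this difference affects the list was not tested. Ribosome biogenesis had 3 of 34 raised (adjusted p = 0.00739, adjusted p = 0.4819 with an estimated correlation). ChREBP targets had 3 of 24 lowered (adjusted p = 0.02015, adjusted p = 0.5442 with an estimated correlation) and ER chaperones 2 of 31, 6 when adjusted over the list alone (adjusted p = 0.000216, adjusted p = 0.5097 with an estimated correlation). limma called 347 raised and 418 lowered genes. Without library C of siChREBP at 0 h 200 passed, 179 of them among these.

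At 12 h siChREBP was used to ask which glucose changes it opposed. Txnip had -0.38±0.28 (1251±290.5 v 1635±382.1 CPM, n = 2 v 3, adjusted p = 0.395). Cyp26b1, which degrades retinoic acid, fell by 3.86±0.27 (9.348±4.338 v 131.3±29.75 CPM, adjusted p = 1.38e-06), Cx3cl1, a chemokine, fell by 3.64±0.40, Gpd1 fell by 1.92±0.22, Tkt fell by 1.53±0.18, Fasn, the fatty acid synthase, fell by 1.49±0.20 and Pklr fell by 1.47±0.18. CCND2 fell by 1.39±0.20, Bhlhe40 fell by 1.35±0.36, Mycn fell by 1.16±0.23, RORC fell by 1.04±0.13 and Gata4 fell by 0.67±0.14. Ins2 rose by 0.90±0.18 (7619±1261 v 4073±555.6 CPM), Mnx1 by 1.73±0.16, Nkx2-2 by 1.29±0.12, Robo2, a guidance receptor, by 2.63±0.21 and Arrdc4 by 0.28±0.09, while Ins1 had 0.54±0.20 (adjusted p = 0.0755). The fall of RPL35A (-5.08±1.58) rests on 1 of the libraries (14.65±20.72 CPM).

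Among lists at 12 h with siChREBP, cholesterol synthesis had 12 of 22 lowered, 14 lowered and 1 raised when adjusted over the list alone, with Idi1 at -1.06±0.13 and Fdps at -0.87±0.13 (adjusted p = 6.098e-07, adjusted p = 0.4659 with an estimated correlation). ChREBP targets had 3 raised and 8 lowered of 24 (adjusted p = 0.001186, adjusted p = 0.4659 with an estimated correlation). Beta cell identity had 12 raised and 4 lowered of 39, 17 and 5 when adjusted over the list alone, with Glis3 at 1.69±0.16 (adjusted p = 0.004606, adjusted p = 0.4659 with an estimated correlation). DNA replication had 1 raised and 5 lowered of 38, with Orc1 at -1.22±0.23 (adjusted p = 0.004753, adjusted p = 0.5922 with an estimated correlation), and ribosome biogenesis 2 raised and 6 lowered of 34, with Npm1 at -0.95±0.10 (adjusted p = 0.02518, adjusted p = 0.5922 with an estimated correlation). G2/M had 4 of 42 raised (adjusted p = 0.007691, adjusted p = 0.6865 with an estimated correlation). limma called 1025 raised and 1183 lowered genes. Leaving out library C of siChREBP at 12 h gave 1016.

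The interaction asked which glucose effects siChREBP altered. Mycn rose less with siChREBP (20.8 v 12.37 CPM, 12 h v 0 h) than with siCtrl, a difference of -2.19±0.33 (adjusted p = 0.00291). Cyp26b1 had -3.97±0.39, Odc1 -1.29±0.18, CCND2 -1.20±0.28 and Mcm5 -1.14±0.23, all smaller rises, and Baiap3, lowered by glucose with siCtrl, had 1.95±0.22. Txnip (0.47±0.40, adjusted p = 0.616), Pklr (-0.82±0.26, adjusted p = 0.114) and RORC (-0.48±0.19, adjusted p = 0.205) were not past the threshold. DNA replication had 5 of 38 lowered, 31 when adjusted over the list alone (adjusted p = 6.317e-19, adjusted p = 0.1253 with an estimated correlation), ribosome biogenesis 5 of 34, 11 when adjusted over the list alone (adjusted p = 4.542e-06, adjusted p = 0.1253 with an estimated correlation), and cholesterol synthesis 1 of 22 (adjusted p = 1.275e-05, adjusted p = 0.4373 with an estimated correlation). Beta cell identity had 2 of 39 raised, 6 when adjusted over the list alone (adjusted p = 1.161e-06, adjusted p = 0.1253 with an estimated correlation). The DNA replication list was already raised by siChREBP at 0 h, so its difference does not come from 12 h alone. By limma 76 effects were raised and 233 lowered, and 119 in total passed without library C of siChREBP at 12 h, 97 of them among the 309. With a replicate block 540 passed.

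How far the experiments shared genes was asked by counting. Of 1324 genes raised at 12 h in exons and tested with siChREBP, 617 were lowered by siChREBP at 12 h against 124.3 by chance, and 10 went the same way. Of 1330 raised genes tested with CA-ChREBP 1152 were raised by it against 227 by chance, and 1 was lowered. Genes raised by glucose, raised by CA-ChREBP and lowered by siChREBP numbered 598 against 21.8 by chance, and those with the reverse signs 255 against 12.2. Across genes the time course correlated with CA-ChREBP at 0.762 and with siChREBP at -0.555. The siCtrl libraries of 12 h stand on both sides when their glucose effect is set against siChREBP: the correlation was -0.670, and -0.448 in simulations without effects. The covariance, which keeps the size of the changes, was -0.3392, and -0.04363 in the simulations. Set against the same siCtrl libraries at 0 h, siChREBP and siRORC both raised 69 genes (6.63 by chance) and both lowered 39 (6.874). Simulations gave on average 0 of either. Changes with siChREBP and siRORC correlated at 0.2409 (0.3981 in the simulations), with a covariance of 0.05334 (0.04306). The single siRNAs also share siCtrl libraries and were not simulated, so a list called with several siRNAs does not give independent results.

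siRORC was used to ask what the nuclear receptor contributed. At 0 h RORC fell by 2.19±0.13 (n = 2 v 3, adjusted p = 4.69e-07), Ids, a lysosomal sulfatase, fell by 1.60±0.11 and Tapbp, of antigen loading, fell by 1.43±0.12, while Gcg, the glucagon gene, rose by 4.41±0.35 (457.2±68.91 v 23.71±11.46 CPM, adjusted p = 6.85e-06), A1cf by 3.30±0.53 and F13b by 2.58±0.44. DNA replication had 16 of 38 raised, 21 when adjusted over the list alone, with Pola1 at 1.06±0.15 (adjusted p = 3.745e-16, adjusted p = 0.2425 with an estimated correlation), and G2/M 3 of 42, 10 when adjusted over the list alone (adjusted p = 4.679e-07, adjusted p = 0.4719 with an estimated correlation). The p53 list had 4 of 16 raised, with Cdkn1a, an inhibitor of the cell cycle, at 1.26±0.32 (adjusted p = 0.00545, adjusted p = 0.3222 with an estimated correlation). Cholesterol synthesis had 2 of 22 lowered, 8 when adjusted over the list alone (adjusted p = 5.348e-06, adjusted p = 0.3222 with an estimated correlation), and ER chaperones 1 raised and 2 lowered of 31, 1 and 11 when adjusted over the list alone (adjusted p = 1.512e-05, adjusted p = 0.4268 with an estimated correlation). Other islet cells had 1 of 3 raised, Gcg (adjusted p = 0.01943, adjusted p = 0.2425 with an estimated correlation), and stroma 1 of 6 (adjusted p = 0.009262, adjusted p = 0.2425 with an estimated correlation). limma called 244 raised and 210 lowered genes, 43 in total without library A of siRORC at 0 h.

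At 12 h with siRORC, RORC fell by 2.09±0.13 (29.13±2.161 v 124±3.017 CPM, n = 2 v 3, adjusted p = 8.93e-07), Plce1, a phospholipase, fell by 2.07±0.21, Lingo4 fell by 2.04±0.35 and S100a4 fell by 2.48±0.54. Gcg rose by 3.04±0.35 (261±77.9 v 31.18±2.992 CPM), Cyp4a8 by 2.04±0.33 and Tp53inp1 by 1.51±0.25. Mycn had -0.36±0.23 (adjusted p = 0.539), CCND2 -0.04±0.20 (adjusted p = 0.965) and Ins2 -0.65±0.18 (adjusted p = 0.0984). Cholesterol synthesis had 9 of 22 lowered, 17 when adjusted over the list alone, with Mvd at -0.89±0.16, Hmgcr, its rate-limiting enzyme, at -0.80±0.15 and Idi1 at -0.76±0.13 (adjusted p = 2.059e-16, adjusted p = 0.2107 with an estimated correlation). ER chaperones had 1 of 31 raised, but 11 lowered when adjusted over the list alone (median -0.29, adjusted p = 5.219e-05, adjusted p = 0.5176 with an estimated correlation). G2/M had 2 of 42 raised (adjusted p = 9.672e-06, adjusted p = 0.5844 with an estimated correlation), the p53 list 2 of 16 (adjusted p = 0.0005995, adjusted p = 0.2412 with an estimated correlation), and the circadian list 1 raised and 1 lowered of 20 (adjusted p = 0.02547, adjusted p = 0.2107 with an estimated correlation). limma called 102 raised and 129 lowered genes, 24 in total without library A of siRORC at 12 h and 567 in a fit of the 2 compared groups alone. For the interaction of siRORC with glucose limma, edgeR and DESeq2 each called 0 genes (424 had an unadjusted p under 0.05, and 1 passed without the filter on low values). DNA replication nevertheless had a median of -0.48, with 12 of 38 lowered when adjusted over the list alone (adjusted p = 3.24e-22, adjusted p = 0.1467 with an estimated correlation). This list was already raised by siRORC at 0 h, so its difference does not come from 12 h alone.

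The libraries labelled siMYCN were compared with siCtrl over both glucose levels (1 library per level). Because Mycn at 0 h goes against the label, directions here describe these libraries and not a loss of Mycn, which had -0.13±0.41 (adjusted p = 0.873). Slc7a11, the cystine transporter, rose by 3.53±0.43 (30.6 v 2.846 CPM, adjusted p = 9.68e-05), Mug1 by 3.24±0.30, Ins2 by 1.30±0.13 (12240 v 5157 CPM), Atf4 by 1.01±0.14 and Ins1 by 0.83±0.14. Vash2, a tubulin peptidase, fell by 4.49±0.59, Id2 fell by 2.53±0.37, Prok2 fell by 1.98±0.34, Txnip fell by 0.96±0.18 and CCND2 fell by 0.45±0.13. The amino acid and ATF4 response had 27 of 37 raised (adjusted p = 2.694e-17, adjusted p = 0.1045 with an estimated correlation) and ER chaperones 14 raised and 1 lowered of 31 (adjusted p = 1.016e-06, adjusted p = 0.5974 with an estimated correlation). Cholesterol synthesis had 8 of 22 raised (adjusted p = 0.0007341, adjusted p = 0.5974 with an estimated correlation), interferon genes 7 of 19 and p53 genes 6 of 16 (both with adjusted p = 0.004682, and adjusted p = 0.307 with an estimated correlation). Ribosome biogenesis and MYC targets had 1 of 34 lowered and were not called (adjusted p = 0.5053). limma called 1187 raised and 1021 lowered genes with this label, 867 in total without siCtrl 12 h A and 1334 with DESeq2.

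siGATA4 was asked about in the same way (1 library per level). Gata4 fell by 0.92±0.13 (adjusted p = 0.000534), Wnk3, a kinase of ion transport, fell by 2.16±0.15 (9.836 v 44.04 CPM), Tmem255b fell by 2.52±0.21 and Bhlhe40 fell by 0.57±0.17. Pcsk1, which cleaves proinsulin, rose by 2.19±0.22 (105.7 v 23.27 CPM), Pgm5 by 2.27±0.24, Ins2 by 1.00±0.13 and Ins1 by 0.60±0.14. Cholesterol synthesis had 9 of 22 lowered, 15 lowered and 1 raised when adjusted over the list alone (adjusted p = 2.986e-08, adjusted p = 0.3847 with an estimated correlation). Hypoxia genes had 1 raised and 6 lowered of 19 (adjusted p = 2.567e-05, adjusted p = 0.3847 with an estimated correlation), and beta cell identity 8 raised and 4 lowered of 39 (adjusted p = 0.02162, adjusted p = 0.7005 with an estimated correlation). limma called 497 raised and 615 lowered genes, 272 in total without siCtrl 12 h A and 594 with DESeq2.

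With siATF4 (1 library per level) Atf4 fell by 1.13±0.14 (adjusted p = 0.000685), Gfra1, a receptor subunit, fell by 1.75±0.35 and CDH6, a cadherin, fell by 1.69±0.34, while Ins1 rose by 0.63±0.14 and Gata4 by 0.50±0.13. Collagen transcripts stood apart: Col1a1 was at 62.37 CPM and at least 220.8-fold higher than with siCtrl, Col3a1 at 21.89 CPM and at least 77.5-fold higher, and Col6a3 at 15.2 CPM and at least 53.81-fold higher. Cholesterol synthesis had 13 of 22 lowered, 19 when adjusted over the list alone (adjusted p = 1.997e-17, adjusted p = 0.1879 with an estimated correlation), and the amino acid and ATF4 response 8 of 37, 13 when adjusted over the list alone (adjusted p = 7.92e-08, adjusted p = 0.1879 with an estimated correlation). G2/M had 5 of 42 raised, 13 when adjusted over the list alone (adjusted p = 2.355e-05, adjusted p = 0.3822 with an estimated correlation), p53 genes 4 of 16 (adjusted p = 0.0003666, adjusted p = 0.1879 with an estimated correlation), and stroma 3 of 8, 6 when adjusted over the list alone (adjusted p = 0.0001928, adjusted p = 0.1972 with an estimated correlation). limma called 376 raised and 326 lowered genes, 86 in total without the siATF4 library of 0 h and 419 with DESeq2.

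With siBHLHE40 (1 library per level) Gcg rose by 4.24±0.24 (564.6 v 29.14 CPM, adjusted p = 4.2e-07), Ptprb, a phosphatase, by 2.33±0.52, Ntsr1, the neurotensin receptor, by 2.28±0.43 and Gata4 by 0.56±0.13. Gatm, of creatine synthesis, fell by 1.89±0.14 and Idi1 fell by 1.76±0.20 (27.72 v 102.3 CPM). Col1a1 was at 27.3 CPM, at least 96.62-fold higher. Cholesterol synthesis had 12 of 22 lowered, 17 lowered and 1 raised when adjusted over the list alone (adjusted p = 1.473e-14, adjusted p = 0.2579 with an estimated correlation), G2/M 10 of 42, 19 when adjusted over the list alone (adjusted p = 5.982e-14, adjusted p = 0.2579 with an estimated correlation), and ER chaperones 1 raised and 6 lowered of 31 (adjusted p = 2.809e-06, adjusted p = 0.3826 with an estimated correlation). Other islet cells had 1 of 3 raised, Gcg (adjusted p = 0.008673, adjusted p = 0.2579 with an estimated correlation), and stroma 3 of 8 (adjusted p = 0.02467, adjusted p = 0.3826 with an estimated correlation). limma called 314 raised and 305 lowered genes, 156 in total without the siBHLHE40 library of 0 h and 382 with DESeq2.

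**Figure D4:**
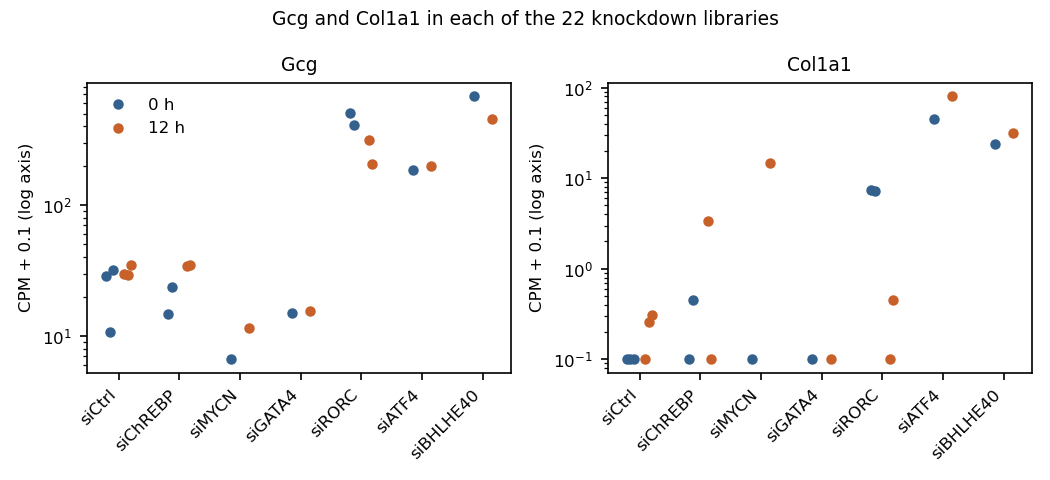
Gcg and Col1a1 in CPM plus 0.1 (log axis) in each of the 22 knockdown libraries, by siRNA and by hours of high glucose; points are libraries. Gcg was at 184.8 to 678.5 CPM in the siRORC, siATF4 and siBHLHE40 libraries and at 10.59 to 34.64 CPM with siCtrl (107.1 to 197.2 CPM in the time course without siRNA, after removal of ribosomal RNA), and Col1a1 reached 80.25 CPM.

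Binding of ChREBP was asked about over 75430 sites. The site with the largest rise at 2 h, on chromosome 3 at 13113552 to 13114052, rose by 6.13±0.45 log2 (245.6±20.35 v 2.73±1.782 signal, n = 2 v 2, adjusted p = 0.000253) and by 6.89±0.45 at 12 h. Others among the 5 largest lay on chromosome 8 at 60004974 (5.82±0.49) and on chromosome 19 at 792589 (5.70±0.68). At 2 h 14841 sites (19.68%) rose and 0 fell, and at 12 h 17206 rose and 4 fell. The median log2 signal over input in libraries A and B was 0.79 and 0.28 at 0 h. It was 1.70 and 1.18 at 2 h, and 1.87 and 1.37 at 12 h. How far the rise came from binding or from the yield of the immunoprecipitation cannot be told apart from these values. The signal as deposited gave a median shift of all sites of 0.89 at 2 h and 0.96 at 12 h, and with TMM over the sites 7625 rose and 231 fell at 2 h and 9348 rose and 1518 fell at 12 h. Without library A of 2 h 6643 sites passed at 2 h, and 6650 passed at 12 h without library A of 12 h. Between 12 h and 2 h limma and edgeR each called 0 ChREBP sites, and 2384 had an unadjusted p under 0.05. Libraries of 1 letter correlated at 0.4829 to 0.6616, and with a replicate block limma called 3132 sites, 33992 at 2 h and 36493 at 12 h against 0 h.

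MED1 was measured over 52362 sites to ask where Mediator followed. The largest rise at 2 h, on chromosome 9 at 7400510 to 7401010, was 4.69±0.45 (114.9±51.18 v 3.575 signal, n = 2 v 2, adjusted p = 5.43e-21). At 12 h it was 6.43±0.45 on chromosome 16 at 81682075 (adjusted p = 7.09e-42). Both p-values use a spread taken from all sites, not that of the libraries at the site. limma called 2149 raised and 109 lowered sites at 2 h and 5746 and 2245 at 12 h, and 578 and 326 between 12 h and 2 h. With TMM over the sites it was 5032 and 1747 at 2 h and 9178 and 8198 at 12 h, and without library B of 0 h 882 sites passed at 2 h. Between 12 h and 2 h TMM gave 3671 raised and 4158 lowered sites, a balance opposite to that of the deposited signal. Every named MED1 site overlapped a ChREBP site.

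**Figure D5:**
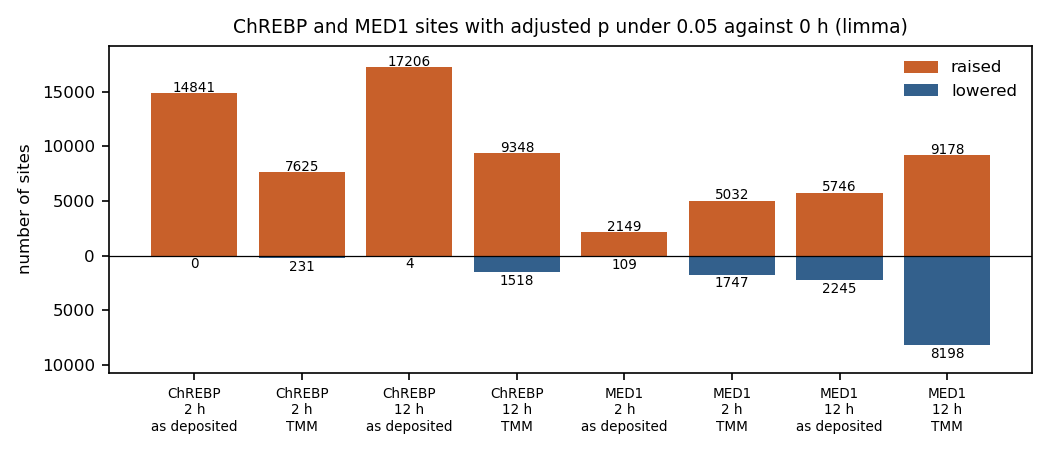
Number of ChREBP and MED1 sites raised (up) and lowered (down) against 0 h with an adjusted p under 0.05 by limma, with the signal as deposited or scaled by TMM over the sites; bars are site counts. ChREBP had 14841 raised and 0 lowered sites at 2 h, while MED1 had 5746 raised and 2245 lowered sites at 12 h.

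Whether the factors shared sites was asked by overlap. Of ChREBP sites 53.77% overlapped a MED1 site (3.373% after a shift by 50000 bp) and 61.41% an open chromatin site (6.135% after the shift). Of MED1 sites 76.55% overlapped a ChREBP site and 84.29% open chromatin, and 35287 ChREBP sites (46.78%) overlapped both. Of 2149 MED1 sites raised at 2 h 2019 (93.95%) overlapped a raised ChREBP site, against 18.45% of unchanged MED1 sites (odds ratio 68.6, 95% interval 57.4 to 82.7 by Fisher's exact test), and with TMM over the sites 3648 of 5032 (72.5%) against 7.121%. At 12 h it was 5084 of 5746 (88.48%) against 15.85% (odds ratio 40.8, 95% interval 37.5 to 44.5), and 0.579% of the lowered MED1 sites. DNase signal, without a test, had a median of 0.90 log2 at 2 h and 1.06 at 12 h at sites of raised MED1, -1.46 and -1.47 at lowered MED1, and 0.21 and 0.21 at raised ChREBP, against 0.06 and -0.25 over all open sites.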

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

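The values of the next paragraph were picked out because the glucose effect differed between siChREBP and siCtrl libraries past an adjusted p of 0.05. Gcg and Col1a1 are given because they lay apart from siCtrl. The tests of collagen in other siRNA libraries and of Gcg were chosen only after the result was seen.

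In 309 genes the glucose effect with siChREBP differed from that with siCtrl, which is what singled them out. Smaller rises, or none, were found for Mycn (-2.19), Cyp26b1 (-3.97), Cx3cl1 (-3.69), Aif1l (-3.22), Tns1 (-2.96), Slc1a2 (-2.80), Odc1 (-1.29), Cdc6 (-1.24), CCND2 (-1.20), Mcm5 (-1.14) and Ncl (-0.91). The difference was positive for Baiap3 (1.95), Pgm5 (1.76), Adora2a (1.69), Oxtr (1.57) and Slc2a5 (1.51). The rise of Mycn with siChREBP already at 0 h makes part of its difference. The DNA replication list also rose with siChREBP at 0 h, so a higher start makes part of its difference too.

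Gcg stood at 184.8 to 678.5 CPM in the 8 libraries of siRORC, siATF4 and siBHLHE40, against 10.59 to 34.64 CPM with siCtrl. Material that brings collagen was excluded as the whole cause, because the siRORC libraries at 12 h held at least 206 CPM of Gcg with at most 0.3465 CPM of Col1a1. Low values were not confined to siCtrl, since all 8 libraries of siMYCN, siGATA4 and siChREBP reached no more than 34.78 CPM. The siRNAs were grouped by their Gcg only after the values were seen, so this cannot exclude chance. Libraries without siRNA, prepared apart, had 107.1 to 197.2 CPM in the time course and 83.68 to 125.7 CPM with the control virus, so whether Gcg was raised in the 8 libraries or lowered in the others is open. Alpha cells remain open: Ttr was at most 1.093% of Gcg and Arx had 0 reads, but both genes are near the floor and no table gives their share in alpha cells.

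Col1a1 was at 23.54 to 80.25 CPM in the siATF4 and siBHLHE40 libraries and at most 0.2099 CPM with siCtrl. Of 12 further fibroblast genes chosen beforehand 11 were measured, and 6 of these were higher in all 4 libraries than in siCtrl of the same letter. Chance gives 6.667% per gene, but genes read in the same libraries are not independent. Among the 6, Fbn1 had at least 3.411 CPM against at most 3.353 with siCtrl, Bgn 0.8528 against 0.6842 and Lox 0.3882 against 0. Thy1, the most abundant of the 11 (28.13 to 106.1 against 48.62 to 75.94 CPM), and Postn were not higher in all 4. Bhlhe40 at 0 h with siBHLHE40 (147.2 CPM) lay within the siCtrl range of 79.69 to 229 CPM, while Col1a1 was at 23.54 CPM. Of the 12 libraries of other siRNAs 4 held Col1a1 above 1 CPM. They were siRORC at 0 h (7.326 and 7.148 CPM), the siMYCN label at 12 h (14.63 CPM) and siChREBP at 12 h B (3.3 CPM, 0 in C). These values argue against knockdown of Atf4 or Bhlhe40 as the only source of Col1a1 in the knockdown libraries. They lie below every siATF4 and siBHLHE40 library, and each of these 2 siRNAs has 1 library per level. A contribution of the knockdown to the higher values therefore cannot be told apart from these libraries. How far fibroblast RNA or the knockdown of Atf4 or Bhlhe40 made the higher values in these 4 libraries cannot be told apart here. The 6 fibroblast genes fall short of the number set beforehand, and neither siRNA has a second library at the same glucose level.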

How the results depend on the processing

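Many counts of changed genes depended on single libraries, and the cause was not tested. The glucose effect with siCtrl, 4562 genes, gave 3394 to 4219 without 1 library, all within 1.5 times. Leaving out 1 library gave, lowest to highest, for exons 8 to 16 genes at 1 h, 17 to 38 at 2 h, 96 to 135 at 4 h, 1021 to 2966 at 12 h and 685 to 2337 between 12 h and 2 h. For introns it gave 39 to 87 at 1 h, 65 to 125 at 2 h, 188 to 291 at 4 h, 608 to 1456 at 12 h and 253 to 701 between 12 h and 2 h. CA-ChREBP gave 2330 to 5058, siChREBP 200 to 881 at 0 h, 1016 to 1968 at 12 h and 119 to 373 for the interaction, and siRORC 43 to 534 at 0 h and 24 to 145 at 12 h. The single siRNAs gave 867 to 2321 for the libraries labelled siMYCN, 272 to 663 for siGATA4, 86 to 400 for siATF4 and 156 to 374 for siBHLHE40. ChREBP sites gave 6643 to 16545 at 2 h and 6650 to 18495 at 12 h, and MED1 sites 882 to 2853 at 2 h and 3537 to 4825 at 12 h. Counts of genes or sites and shares of sites were compared in size only, so a turn of direction could not show. For MED1 between 12 h and 2 h the deposited signal gave 578 raised and 326 lowered sites, and TMM 3671 and 4158. Over the results of comparisons, 186 values of alternatives other than leaving out 1 library were the same. Another 51 moved by more than 1.5 times or beyond the interval, and no odds ratio of shared genes reversed. Over single genes, sites and lists 6036 of these values were the same, 396 weaker, 58 stronger and 6 moved, and without 1 library 2904 were the same, 695 weaker, 12 stronger and 3 moved.

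The replicate block pairs libraries by letter. For glucose with siCtrl it gave 4996 genes and changed no call of a named gene. The decision not to use this pairing was made with the blocked counts already known. With the block exons gave 39 genes at 1 h, 150 at 2 h, 537 at 4 h and 2964 between 12 h and 2 h. Introns gave 191 at 1 h, 468 at 2 h, 939 at 4 h and 1130 between 12 h and 2 h. The block gave 540 for the interaction of siChREBP with glucose, 413 for siATF4 over all 22 libraries (831 without a letter term and 702 over 12 libraries), 33992 ChREBP sites at 2 h and 36493 at 12 h, 3132 ChREBP sites between 12 h and 2 h, and 6920 MED1 sites at 2 h and 17523 at 12 h. A crossed pairing for CA-ChREBP gave 4729 genes, 2570 raised and 2159 lowered.

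DESeq2, added after the data were seen, gave 42 genes at 1 h and 132 at 2 h in exons, 178 and 388 in introns, 1334 for the siMYCN label, 594 for siGATA4, 419 for siATF4 and 382 for siBHLHE40. Without the filter on low values introns gave 67 at 1 h and 143 at 2 h, siGATA4 741, siBHLHE40 408 and the glucose effect altered by siRORC 1. The 2 compared groups alone gave 567 for siRORC at 12 h. TMM over the sites gave 7856 ChREBP sites at 2 h and 10866 at 12 h, and 6779 and 17376 MED1 sites, and of the raised MED1 sites 72.5% at 2 h and 65.46% at 12 h overlapped a raised ChREBP site. MED1 sites above the median signal gave 4351 at 12 h. Asking for an overlap of 0.5 of the shorter site, or using the stronger part of each table, gave 49.78% and 56.41% for ChREBP over MED1, 50.33% and 70.47% for ChREBP over DNase, 71.68% and 80.09% for MED1 over ChREBP, 71.8% and 86.24% for MED1 over DNase, 32.84% and 43.59% for DNase over ChREBP, and 32.49% and 37.54% for DNase over MED1. The stronger part of the first table alone, added after the data were seen, gave 79.66%, 80.77%, 86.5%, 89.41%, 59.38% and 60.43% in the same order. Alternatives that need genes near sites, such as those within 25 kb, were not run because no rn5 annotation was at hand.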

Other observations

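Late changes were past the threshold at 12 h against 0 h and in the same direction between 12 h and 2 h. No earlier change was needed. They were counted more often than brief ones, which turned back by 12 h. A brief change needed a call at 1 h or 2 h, and 61 exon genes passed at 2 h against 2433 at 12 h. The classes therefore had unequal chances to be filled, and their difference was not tested. In exons 860 genes rose late, among them Txnip and Bhlhe40, raised already at 1 h, and 581 fell late, while 2 rose briefly. In the DNA replication list 32 of 37 genes rose late, as did 11 of the G2/M list, 14 of the ribosome biogenesis list and 7 of the ChREBP list. In introns 358 rose late. At both 2 h and 12 h, without a difference between these times, 108 were raised and 47 lowered in introns, and 14 and 12 in exons.

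The test of other splits below was chosen only after the result was seen, and both tests of intron reads were written beforehand.

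The genes raised in introns at 1 h may include reads from small RNA genes that lie in introns. Such genes lay in 22.62% of the raised genes against 5.553% of the others (odds ratio 4.971, 95% interval 2.80 to 8.45 by Fisher's exact test). More unspliced RNA that later matures fits as well, since the median exon change of the raised genes at 12 h was 1.82, above all 10000 random lists. The 0 h libraries served both to pick these genes and in their exon change, while the random lists were not picked on them. Exon reads at 12 h also hold RNA made after 1 h. When split, without a test, 19 genes with a small RNA gene had an exon median of 0.17 at 12 h and 59 without one had 2.04. It is a hypothesis that the first set, with Tada3 as a possible case, reflects small RNA production and the second set transcription, and sequencing of small RNA at 1 h would test it.

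Glucose with siCtrl changed 4562 genes. The 6 siCtrl libraries allow 10 splits into 3 and 3, the highest other split gave 0 genes, and so only 1 split reached the real value, which with 10 splits can never be a share under 0.1. Every other split mixes libraries of 0 h and 12 h, so a glucose effect widens its spread and lowers its count. The splits also leave the letter pairs aside.

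A hypothesis from these data is that ChREBP is needed for part of the response at 12 h. The count of genes with an altered glucose effect, 309, and 119 without library C of siChREBP at 12 h, might rise with a deeper knockdown, because Mlxipl stayed at 48.83%. Some of these differences arise in part from changes with siChREBP already at 0 h, as for Mycn. Loss of Mlxipl by gene editing, followed over the same 12 h, would test the hypothesis.

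Another hypothesis is that ChREBP recruits MED1, since 93.95% of the MED1 sites raised at 2 h overlapped a raised ChREBP site. The share could partly reflect scaling, as it was 72.5% with TMM over the sites. MED1 binding after siChREBP, with spike-in chromatin, would test it.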
